A study of Drosophila melanogaster with 4 samples.

How the data were processed

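Small RNA of 18 to 30 nt was cut from a gel and sequenced on an Illumina GAII, per the labels' protocols, from S2 cells kept at 25 °C in medium with 10% serum and transfected with 20 µg of double-stranded RNA. Groups were taken from the sample titles, which give the target of the double-stranded RNA and the oxidation. There were 4 groups of 1 library each. The deposited tables list each distinct read with its count, a whole number that repeats on every line giving a genomic place of the read, so the count was taken once per sequence. The last column of the deposited tables gives the length of the 5′ part of the read that matches the genome, which was at least 15 nt in every line. The aligner, its version, the genome build and any filters applied by the authors are not given in the sources used here. Chromosome names are those of release 5 of the fly genome, while the reference annotation used here is of release 6, so positions were not converted between releases and the reference was used for distances between genes. The longest read had 26 nt, so longer RNAs of the gel range were not measured. Sequences that do not match the genome over 15 nt from the 5′ end were not analysed here.

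Mature miRNA arms were placed from 101 sequences typed from memory. A placement was kept where its distance to another placed miRNA gene differed from that in the reference by at most 150 nt (the largest difference was 35 nt). This named 92 arms and rejected 1 placement, and the most frequent 5′ end with at least 100 reads 30 to 70 nt away on the same strand named 37 further arms as the other arm of a hairpin, 129 in all. The 5′ arms of the mir-276 paralogs have the same reads and were counted as miR-276-5p. Reads starting within 2 nt of an arm's 5′ end were assigned to it, and reads of several arms were divided among them. Arms with over 50% of their reads shared with another arm, miR-2c-3p and miR-13a-3p, were left out, and miR-2a-3p and miR-2b-3p keep some uncertainty from shared reads. The mean genome-matching length of an arm also falls with mismatches inside the read, as in miR-305-5p, where 10.7% and 10.2% of unoxidized reads match over 16 nt.

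No test across conditions was run, since each group holds 1 library. A fit of label plus oxidation would treat the oxidized and unoxidized pairs as replicates and was not used here. An arm was called longer or shorter where its mean genome-matching length differed by 0.3 nt or more, with the 95% counting interval of the difference excluding 0 and at least 1000 reads in each library. Abundance was the share of miRNA reads, compared for arms with at least 100 reads over both libraries against a limit of 2-fold. Intervals of shares are exact binomial, intervals of RPM exact Poisson, and a count of 0 allows up to 3 counts. PCR reads are not independent molecules, so all intervals and floors cover counting error only. A list of at least 3 tested arms was described by the percentile of its median length change among 10000 random lists. Each member was drawn from the 10 arms outside the list nearest in reads. Major and minor arms were set by the reads of both unoxidized libraries.

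The comparisons with their limits, the 9 fixed lists and the rule for named arms were chosen before the data were examined. The window search, the read classes that replaced annotated ones, the luciferase count and most tests of explanations were chosen after the data were seen. The rule named the 15 largest rises and 5 largest falls in length past the limit in the unoxidized pair, 5 each way in the oxidized pair and for the difference of differences, the 5 highest and 5 lowest abundance changes past 2-fold in each pair, the 8 most enriched and 8 most depleted arms after oxidation, and the measured members of the lists. Of the lists, 6 hold miRNA arms: Nibbler substrates, abundant S2 miRNAs, the K-box family, Argonaute2-loaded arms, mirtrons and markers of other cell types. The mirtrons miR-1004-3p, miR-1005-3p, miR-1007-3p and miR-1008-3p and the arm miR-2b-1-5p were not placed. Transposons, ribosomal, transfer and small nuclear RNA, the flamenco locus and endogenous siRNA loci other than hpRNA:CR46342 were not analysed here, because the reference has no annotation for the coordinates of the files. For the same reason, exons of nibbler were replaced by a search for 500-nt windows with 100 or more fully matching reads of 1 genomic place in an oxidized library and 0 in the other. Luciferase-matching reads share at least 18 nt with a humanized Renilla luciferase sequence written from memory.

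The length step was tested on simulated data for the unoxidized comparison. Among 49 arms, 0 of 37 without a simulated shift were called, 0 of 3 with a shift of 0.2 nt, and 3 of 3 with each of 0.4, 0.6 and 1.0 nt. The abundance step was tested for the same comparison on 82 arms, where 0 of 70 unchanged arms and 3 of 3 arms at each of 4-fold and 3-fold up and down were called. Alternatives covered the 5′ start, read minimums of 200 and 5000, fully matching reads, the full read length, arms with 1 genomic place, thinning to the shallowest library, the most frequent length, limits of 0.2 and 0.5 nt, scaling to all reads, to hairpin reads or by the TMM method of edgeR, minimums of 1000 reads or none with 0.5 read added, and read subsets for classes and tails. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16 were used.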

Results

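Small RNAs were sequenced from Drosophila S2 cells, a cell line of embryonic origin, after transfection of double-stranded RNA against nibbler (CG9247) or against luciferase, a reporter gene that flies lack. Nibbler is a 3′-to-5′ exoribonuclease, and the title of the series states its question, whether it trims the 3′ ends of microRNAs (miRNAs). Libraries were made with and without periodate oxidation of the RNA, which removes small RNAs with a free 3′ end and keeps those with a 2′-O-methyl group there, largely the small interfering RNAs (siRNAs) and the miRNAs bound to Argonaute2. The 4 libraries form 4 groups with 1 library each, so no difference below has a replicate check, and the counting intervals describe these libraries and not the conditions. Total read counts were 8615658 in the luciferase-labelled unoxidized library, 9593068 in the nibbler-labelled unoxidized library, 6108182 in the luciferase-labelled oxidized library and 5012260 in the nibbler-labelled oxidized library.

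The targeted genes were examined first, because double-stranded RNA leaves siRNAs of its own sequence. Reads matching luciferase reached 96697 RPM (reads scaled to the size of the library) in the luciferase-labelled oxidized library (95% interval 96450 to 96944) and 84.6 RPM in its nibbler-labelled counterpart. In the unoxidized libraries they reached 10456 and 3.75 RPM. The opposite excess of nibbler reads in the nibbler-labelled libraries was not seen. Of 457 windows of 500 nt with at least 100 reads in the luciferase-labelled oxidized library, 2 adjacent windows held 0 reads in the nibbler-labelled oxidized library, and they lay on chromosome 2L at 21161001 to 21162000 in the release 5 coordinates of the files. At the same distance from mir-1, the reference annotation of release 6 places nibbler (Nbr) and its neighbour Pld3, a match by spacing and not by sequence, so the exons were not assigned. This stretch gave 815 reads in the luciferase-labelled oxidized library, 393 on the plus and 422 on the minus strand, with 83.8% of them 21 nt long. It gave 65 reads in the luciferase-labelled and 1 read in the nibbler-labelled unoxidized library. The 0 reads of the nibbler-labelled oxidized library allow up to 0.599 RPM, against 133 RPM in the luciferase-labelled one. In the 10 kb on each side, the 4 libraries held 47, 71, 158 and 114 reads, in the order luciferase-labelled then nibbler-labelled, unoxidized then oxidized. Of 435 windows with at least 100 reads in the nibbler-labelled oxidized library, 0 were empty in the luciferase-labelled one. The luciferase-matching reads thus went with the luciferase label, while the reads over the stretch of 2L went against the label of the nibbler RNAi libraries. Groups are therefore called nibbler-labelled and luciferase-labelled throughout, and that nibbler was the other target rests on the labels.

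miRNAs dominated the unoxidized libraries and reads of 21 nt the oxidized ones. The most frequent length was 23 nt in the unoxidized libraries, with 48.4% of luciferase-labelled and 50% of nibbler-labelled reads, largely because bantam-3p, a growth-promoting miRNA, supplied 53.6% and 54.6% of all miRNA reads. After oxidation the most frequent length was 21 nt, with 80.6% and 80.3% of reads. Named miRNA arms held 77.8% of luciferase-labelled and 76.5% of nibbler-labelled reads before oxidation, and 5.56% and 6.50% after it. The exact 95% binomial intervals of these shares were narrower than 0.1 percentage points.

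**Figure D1:**
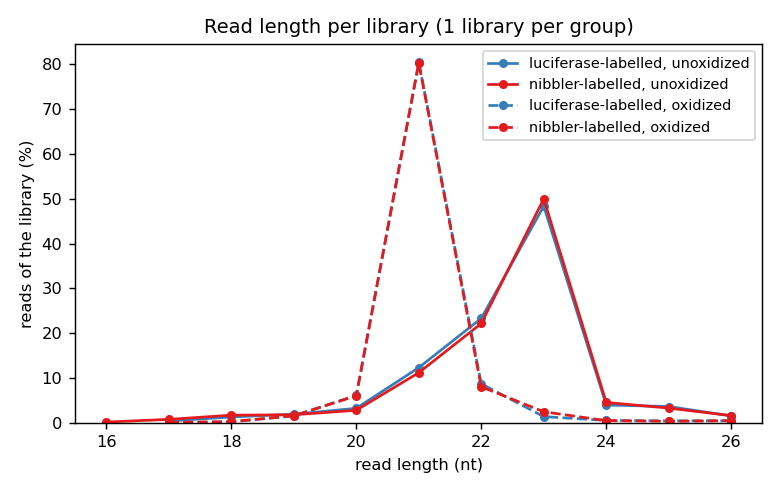
Share of reads (%) at each read length (nt) in each of the 4 libraries, blue for luciferase-labelled and red for nibbler-labelled, solid for unoxidized and dashed for oxidized. The unoxidized libraries peak at 23 nt (48.4% and 50%) and the oxidized libraries at 21 nt (80.6% and 80.3%).

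The main comparison asked which miRNAs had other 3′ ends in the nibbler-labelled unoxidized library. miR-34-5p, an ageing-related miRNA, was the most affected arm, with a mean genome-matching length of 23.4 nt against 22.3 nt in the luciferase-labelled library, a rise of 1.04 nt (95% counting interval 1.02 to 1.06). Its 24-nt form rose from 39.0% to 67.7% of its reads while the 21-nt form fell from 16.9% to 3.5%. The next arms were miR-317-3p, from a locus near mir-34 on chromosome 3R, which was longer by 0.455 nt, and miR-305-5p, which was longer by 0.409 nt. The 24-nt form of miR-305-5p rose from 67.2% to 78.1%, and its 21-nt form fell from 8.3% to 2.0%. In all, 9 of 49 arms with at least 1000 reads in each library were longer by 0.3 nt or more with an interval excluding 0, and 0 were shorter by that much.

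The other 6 arms past that limit were miR-2a-3p (0.40 nt), miR-263a-5p (0.382 nt), miR-996-3p (0.367 nt), miR-2b-3p (0.356 nt), miR-190-5p (0.329 nt) and miR-9b-5p (0.317 nt). miR-2b-3p and miR-996-3p also changed their most frequent length, from 22 to 24 nt and from 21 to 22 nt, while the most frequent form of miR-34-5p, miR-305-5p, miR-263a-5p, miR-190-5p and miR-9b-5p was 24 nt in both libraries. In release 5 coordinates the most abundant reads came from 3R at 5926674 to 5926697 for miR-34-5p, 3R at 5916903 to 5916924 for miR-317-3p, 2L at 7425979 to 7426002 for miR-305-5p and 2L at 11953463 to 11953486 for miR-263a-5p, each within the arm of a miRNA hairpin. The remaining arms moved little. Of the 49 arms, 33 moved by less than 0.1 nt, the lowest value was -0.0526 nt in miR-304-5p, and the median over all 49 was 0.0473 nt.

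**Figure D2:**
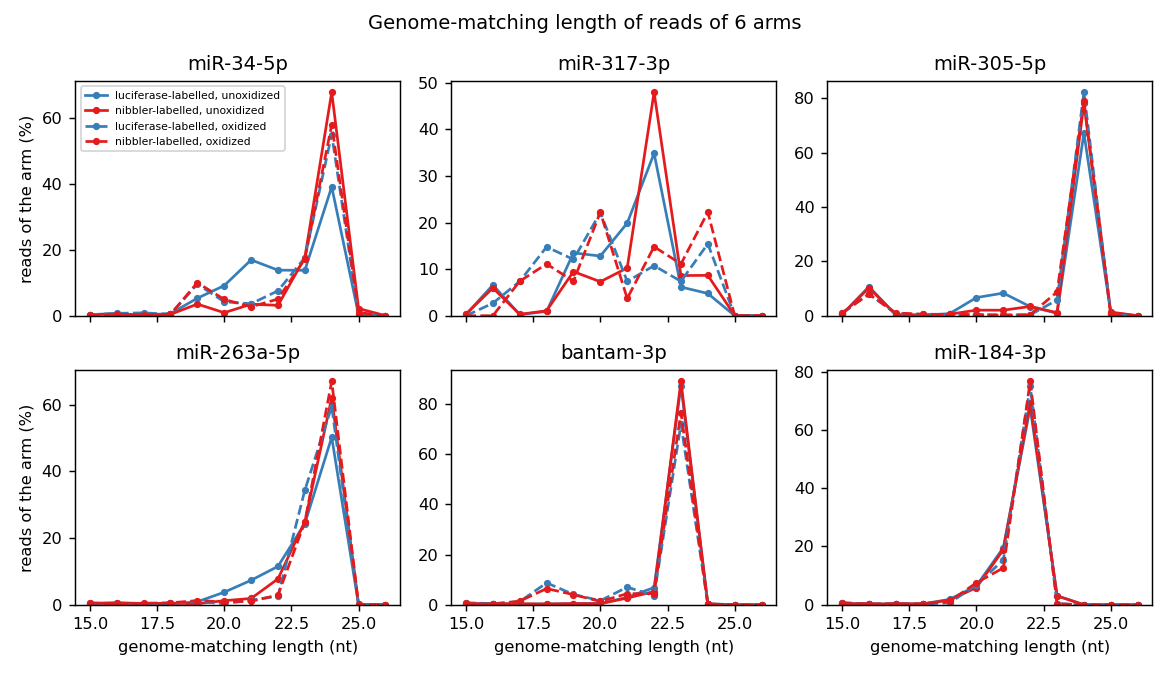
Share of the reads of an arm (%) at each genome-matching length (nt) for 6 arms in the 4 libraries, colours and line types as in the plot of read lengths. In unoxidized libraries the 24-nt form of miR-34-5p holds 39.0% of luciferase-labelled and 67.7% of nibbler-labelled reads, whereas the 23-nt form of bantam-3p holds 87.3% and 89.1%.

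Among arms listed from memory of reported Nibbler substrates, 7 of 9 had enough reads and 5 were called longer, namely miR-34-5p, miR-317-3p, miR-305-5p, miR-263a-5p and miR-190-5p. The other tested members gave 0.261 nt for miR-11-3p and 0.124 nt for miR-7-5p, miR-12-5p gave 0.281 nt with 526 and 590 reads, and miR-10-5p had 27 and 30 reads. The list median was 0.382 nt (95% counting interval 0.335 to 0.418), above all of the 10000 random lists matched on reads. This list draws partly on work with libraries of this kind, so it is not independent evidence of its direction. In the K-box family, miRNAs that share a seed matching the K box of Notch target genes, 2 of 5 tested arms were called longer, miR-2a-3p and miR-2b-3p, against -0.0116 nt for miR-13b-3p and -0.0524 nt for miR-308-3p. The family median of 0.261 nt lay at percentile 94.3 of random lists. Of 15 abundant S2 miRNAs, miR-996-3p and miR-9b-5p were called longer, and the remaining 13 lay between -0.0227 nt (miR-995-3p) and 0.0734 nt (miR-9c-5p), with bantam-3p at 0.0062 nt, miR-184-3p at 0.0266 nt and miR-8-3p at 0.0624 nt. The median of this list, 0.0220 nt, lay at percentile 0.12 of random lists. Those lists were drawn from arms outside this list, which include the 5 Nibbler list arms called longer, and none of them came near bantam-3p in reads. The percentile therefore partly restates how the lists were divided. Of arms known to load Argonaute2, 0 of 5 were called longer, with bantam-5p at 0.136 nt, miR-277-3p at 0.0702 nt, miR-276-5p at 0.0597 nt, miR-8-5p at 0.0463 nt and miR-13b-2-5p at -0.0487 nt, and the list median lay at percentile 69.2. The mirtron miR-1003-3p, cut from an intron by splicing, gave 0.0202 nt. With the most frequent length in place of the mean, 5 arms moved by at least 1 nt, of which 2 were among the 9, and the Nibbler list median was 0 nt. With a limit of 0.5 nt miR-34-5p was the only arm left.

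The oxidized pair asked whether the 3′ ends of miRNA reads left after oxidation differed between the labels. Whether these reads carried a 2′-O-methyl group was not measured. Some tested arms were residues of strong depletion, such as bantam-3p, which fell from 417114 to 1196 RPM in the luciferase-labelled libraries. Of 23 arms tested, 1 was called longer and 0 shorter. Of the 9 arms lengthened before oxidation, miR-305-5p and miR-263a-5p had enough oxidized reads for this test, and neither was called. miR-305-5p changed by -0.0578 nt and miR-263a-5p by -0.0207 nt, with intervals that included 0 and means near 23 nt in both libraries, while miR-11-3p changed by 0.132 nt. The arm called longer was miR-995-3p, with 20.5 nt against 20.0 nt, a rise of 0.554 nt (95% counting interval 0.502 to 0.606). Its 19-nt form held 38.2% of luciferase-labelled oxidized reads and 9.6% of nibbler-labelled ones, and under 2% in either unoxidized library. miR-34-5p, with 689 and 930 oxidized reads, fell below the read minimum, and its change was 0.117 nt with an interval of -0.0669 to 0.30.

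The 2-by-2 design also gives a difference of these differences for 21 arms with 1000 reads in every library. The oxidized change was lower than the unoxidized change by 0.3 nt or more in miR-305-5p (-0.467 nt, interval -0.544 to -0.390) and miR-263a-5p (-0.403 nt, interval -0.487 to -0.319), and higher in miR-995-3p (0.577 nt, interval 0.523 to 0.630). These 3 arms became 5, of which 4 lower, with a minimum of 200 reads, 1 lower arm (miR-305-5p) with 5000 reads, and 1 higher arm (miR-995-3p) with a limit of 0.5 nt. Smaller differences were -0.130 nt for miR-11-3p, -0.111 nt for miR-988-3p and -0.0622 nt for miR-2b-2-5p on the low side. On the high side were bantam-3p at 0.188 nt, miR-305-3p at 0.136 nt, miR-276-5p at 0.133 nt and miR-276a-3p at 0.0952 nt. The median over the 21 arms was -0.0223 nt. The Nibbler substrate list had only 3 tested members in the oxidized pair, with a median of -0.0207 nt (interval -0.0682 to 0.0455) at percentile 2.01 of random lists, and the median became 0.0847 nt when only fully matching reads were used. Abundant S2 miRNAs had 1 of 7 called longer and a median of 0.113 nt, at percentile 99.4, and Argonaute2-loaded arms had 0 of 5 called longer and a median of 0.0426 nt, at percentile 62.2.

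**Figure D3:**
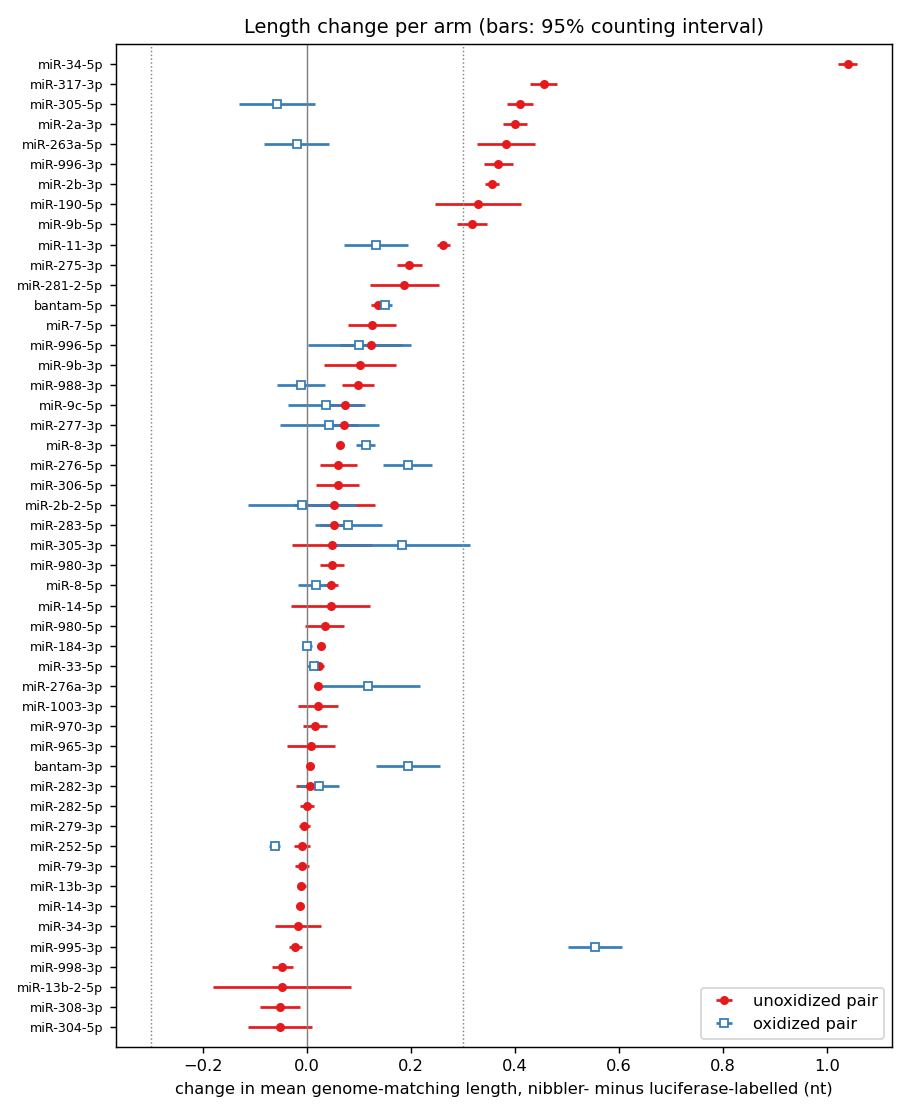
Change in mean genome-matching length (nt), nibbler-labelled minus luciferase-labelled, for the 49 arms tested in unoxidized libraries (red circles) and, where tested, in oxidized libraries (blue squares); bars are 95% counting intervals and dotted lines mark 0.3 nt in either direction. The 9 arms beyond 0.3 nt run from miR-9b-5p (0.317 nt) to miR-34-5p (1.04 nt), and the oxidized values of miR-305-5p and miR-263a-5p lie near 0.

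Abundance was compared as the share of miRNA reads. In the nibbler-labelled unoxidized library, miR-79-3p was 12.3-fold lower (log2 change -3.62, 95% counting interval -3.64 to -3.60) and miR-317-3p was 5.68-fold lower (log2 -2.51). Lower shares were also seen for miR-252-5p (log2 -1.60), miR-4-3p (log2 -1.58) and miR-306-3p (log2 -1.39). Higher shares were seen for miR-279-5p (log2 3.25, 37 against 386 reads), miR-970-5p (log2 3.13, 24 against 230 reads), bantam-5p (log2 1.66), miR-276-5p (log2 1.31) and miR-286-3p (log2 1.20). The other 86 of the 96 arms with at least 100 reads stayed within 2-fold, bantam-3p, miR-184-3p, miR-8-3p and miR-14-3p among them.

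The other arms of these hairpins, chosen after the changes were seen, moved less. miR-79-5p had a log2 change of -0.81, miR-317-5p of -0.35 and miR-306-5p of -0.10, while miR-252-3p at -0.97 fell nearly as far as the limit. The partners of the raised arms, miR-279-3p, miR-970-3p and bantam-3p, had log2 changes of -0.07, -0.62 and 0.03. Of the 9 arms called longer, miR-317-3p was the only arm that also changed 2-fold, while miR-34-5p reached log2 0.92 and miR-2b-3p log2 -0.75. In the Nibbler substrate list 1 of 8 measured arms was lower (miR-317-3p), and in the list of Argonaute2-loaded arms 2 of 6 were higher (bantam-5p and miR-276-5p). None of 15 abundant S2 miRNAs, 6 K-box miRNAs or 3 mirtrons changed 2-fold. TMM scaling gave 11 arms past 2-fold, a minimum of 1000 reads gave 5 past 2-fold, and no minimum gave 18.

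In the oxidized pair, 6 of 56 arms changed 2-fold. miR-79-3p (log2 -3.26), miR-317-3p (log2 -2.41), miR-252-5p (log2 -1.68) and miR-306-3p (log2 -1.28) were lower, and bantam-5p (log2 1.53) and miR-995-5p (log2 1.82, 44 against 149 reads) were higher. Of the arms changed in the unoxidized pair, 6 were measured here, 6 had the same sign and 5 also passed 2-fold, the remaining arm being miR-276-5p with a log2 change of 0.71. Across the 56 arms, which are not independent replicates, the changes of the pairs correlated with a Pearson coefficient of 0.885 and a Spearman coefficient of 0.713. The pairs share no library, and whether the libraries of a label came from the same cells is not given in the sources used here. Scaling to all reads or by TMM moved all oxidized changes by 0.23 or 0.16 on the log2 scale and gave 6 calls each, and scaling to hairpin siRNA reads moved them by -0.11 and gave 7. The number past 2-fold was 3 with a minimum of 1000 reads and 27 with no minimum.

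**Figure D4:**
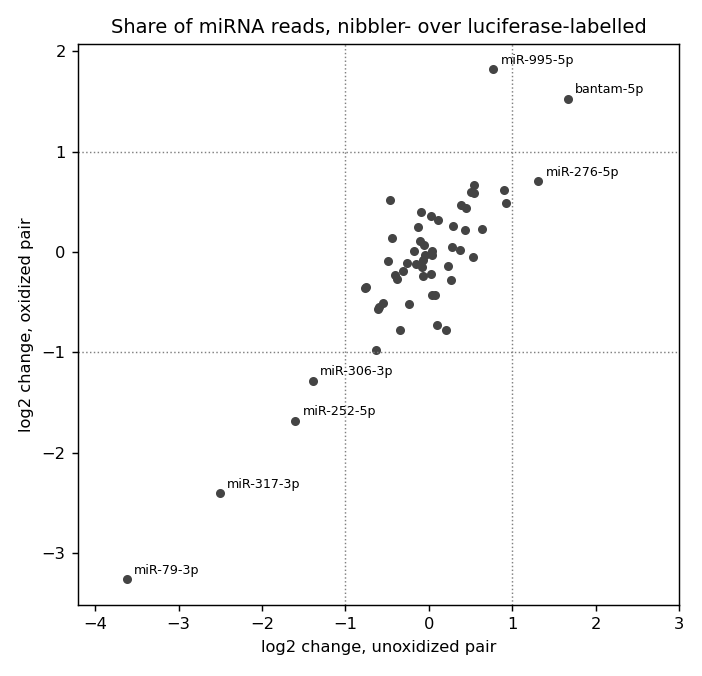
Log2 change in the share of miRNA reads, nibbler-labelled over luciferase-labelled, in the unoxidized pair (horizontal axis) and the oxidized pair (vertical axis) for 56 arms; dotted lines mark 2-fold. miR-79-3p lies at -3.62 and -3.26, and bantam-5p at 1.66 and 1.53.

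As shares of miRNA reads, most minor arms rose with oxidation and most major arms fell, these being the less and the more abundant arm of a hairpin. In the luciferase-labelled pair 20 of 34 minor arms were past 2-fold higher and 5 lower, and 23 of 37 major arms were lower and 10 higher, whereas as shares of all reads the minor arms also had a negative median, -1.95. Among luciferase-labelled libraries the most enriched arms were miR-308-5p (log2 7.13), miR-33-3p (6.45), miR-988-5p (6.09), miR-966-5p (5.62), miR-252-5p (5.36), miR-2a-2-5p (4.41), miR-184-5p (4.28) and miR-2a-1-5p (4.04). The most depleted arms were miR-317-3p (log2 -5.49), miR-304-5p (-4.80), miR-308-3p (-4.76), bantam-3p (-4.64), miR-980-3p (-4.55), miR-14-3p (-4.22), miR-970-3p (-4.04) and miR-282-5p (-3.97). The median log2 change in the share of miRNA reads was 1.85 over the minor arms and -2.05 over the major arms. The difference between minor and major arms was 3.90 (95% counting interval 3.71 to 4.03), and the minor arm exceeded the major arm in 25 of 32 hairpins. Arm roles were set by unoxidized reads, which are also the denominator of this ratio, so minor arms tend to score higher by construction. With a minimum of 1000 reads the minor-arm median was 3.18 and the difference 5.99. That minimum sums both libraries, so a minor arm can pass it through its oxidized reads, as miR-33-3p did with 834 unoxidized and 3696 oxidized reads. It is therefore not an independent check. miR-252-5p and miR-33-5p, at log2 5.36 and 3.23, were major arms with strong enrichment.

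Nibbler-labelled libraries gave a minor-arm median of 1.51, a major-arm median of -2.22 and a difference of 3.73, with the minor arm above the major arm in 27 of 33 hairpins. With a minimum of 1000 reads the minor-arm median was 2.69 and the difference 5.30. Here 2 minor arms had 0 oxidized reads, and placing them at the bound of 3 reads left the median at 1.51. Across 80 arms measured under both labels the log2 changes had a Pearson coefficient of 0.980. As shares of miRNA reads, 5 of 6 Argonaute2-loaded arms were higher under either label. In the luciferase-labelled pair miR-33-3p, bantam-5p (log2 3.78), miR-13b-2-5p (3.70), miR-276-5p (3.67) and miR-8-5p (1.80) were past 2-fold and miR-277-3p was at 0.79. As shares of all reads there, miR-8-5p fell from 3949 to 986 RPM and miR-277-3p from 3631 to 449 RPM. bantam-5p (5966 to 5856 RPM), miR-13b-2-5p (157.5 to 145.9 RPM) and miR-276-5p (263 to 240 RPM) fell slightly, and luciferase-matching reads lower all shares in that oxidized library. In the nibbler-labelled pair bantam-5p (18571 to 19728 RPM) and miR-13b-2-5p (129.2 to 158.0 RPM) rose, while miR-276-5p, miR-8-5p and miR-277-3p fell. miR-33-3p rose in both pairs, from 96.8 to 605 RPM in the luciferase-labelled and from 84.3 to 713 RPM in the nibbler-labelled pair. In K-box miRNAs 5 of 6 were lower, with miR-11-3p the exception at log2 -0.50 in the luciferase-labelled pair, and among abundant S2 miRNAs 10 of 15 were lower and 3 higher (miR-33-5p, miR-9c-5p and miR-995-3p). Of 8 Nibbler substrates 4 were higher in the luciferase-labelled pair, led by miR-190-5p (3.84) and miR-263a-5p (3.67), and 3 were lower, miR-317-3p, miR-7-5p (-2.87) and miR-34-5p (-1.80), while the nibbler-labelled pair had 3 higher and 3 lower. The mirtrons miR-1003-3p and miR-1006-3p were lower in the luciferase-labelled pair, with log2 values of -1.16 and -1.87, and miR-1003-3p stayed within 2-fold in the nibbler-labelled pair, at -0.95. As shares of all reads every value changed by -3.81 in the luciferase-labelled and -3.56 in the nibbler-labelled pair, which left 5 and 6 arms past 2-fold higher and turned positive values below that size negative, so enrichment holds relative to other miRNAs. TMM scaling changed the values by -1.18 and -0.99 and scaling to hairpin reads by -6.81 and -6.76, with 22 and 25 arms higher under the first and 0 under the second.

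**Figure D5:**
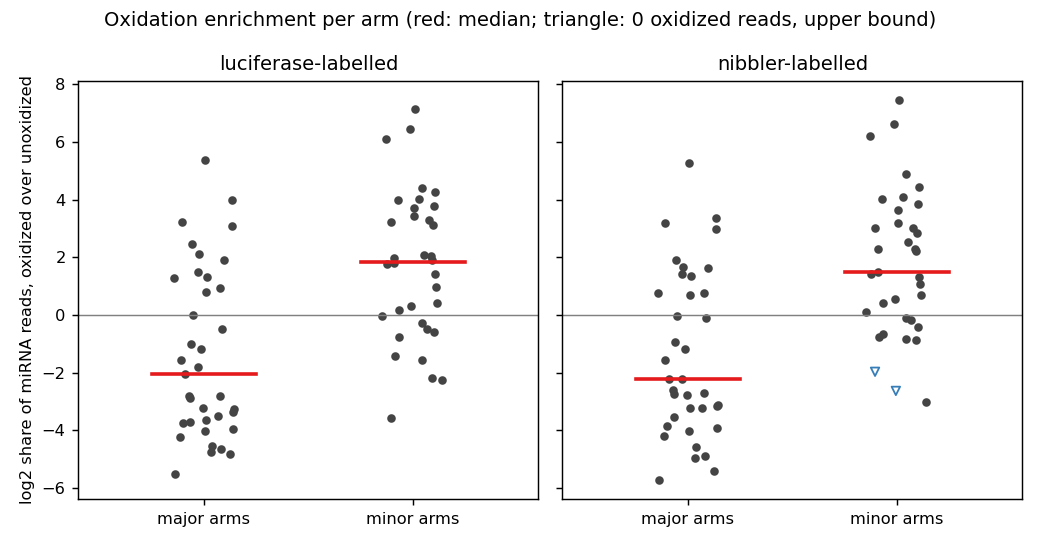
Log2 ratio of the share of miRNA reads, oxidized over unoxidized, for the major and minor arms of hairpins in luciferase-labelled (left) and nibbler-labelled (right) libraries; points are arms, red lines are medians and triangles are arms with 0 oxidized reads, drawn at the bound of 3 reads. Minor arms have medians of 1.85 and 1.51 and major arms of -2.05 and -2.22.

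siRNA classes were compared next. The long hairpin RNA hpRNA:CR46342, a known source of endogenous siRNAs at X 4815735 to 4821561 in release 5 coordinates, carries 20 copies of the siRNA esi-2.1 (TTGACTCCAACAAGTTCGCTCC). It gave 0.20% of luciferase-labelled and 0.220% of nibbler-labelled unoxidized reads, and 1.6% and 2.02% of oxidized reads. The mean genome-matching length of esi-2.1 was 21.7 nt in both unoxidized libraries and 21.9 nt in both oxidized libraries. Reads with 10 or more genomic places rose from 4.35% to 53.0% with oxidation in luciferase-labelled and from 4.90% to 58.7% in nibbler-labelled libraries. Mitochondrial reads fell from 0.143% to 0.0172% and from 0.153% to 0.0195%, and reads with 3 or more unmatched bases made up 6.13%, 6.23%, 17.2% and 18.1% of the libraries in the order given for the flanks above. Luciferase-matching reads made up 9.67% of the luciferase-labelled oxidized library, which lowers every other class there.

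Reads with bases after the genome-matching part, called tailed here, were nearly as frequent under either label. A mismatch inside a read also leaves such bases, so they need not be untemplated 3′ tails. Tailed reads made up 4.91% of luciferase-labelled and 5.12% of nibbler-labelled unoxidized miRNA reads (exact 95% binomial intervals 4.89% to 4.92% and 5.11% to 5.14%), and 4.25% and 4.52% of oxidized ones. Tails of A alone fell with oxidation from 0.982% to 0.233% in luciferase-labelled and from 0.973% to 0.204% in nibbler-labelled libraries. Tails of U alone made up 0.737%, 0.826%, 0.606% and 0.583%, in the order luciferase-labelled then nibbler-labelled, unoxidized then oxidized. Tails of other or mixed bases were the largest part in each library, at 3.19%, 3.33%, 3.41% and 3.73% in the same order. These pooled shares depend on the mix of arms. In luciferase-labelled libraries bantam-3p, with 0.059% U tails before oxidation, supplied 53.6% of miRNA reads then and 2.15% after it. U tails rose there in miR-996-5p (2.32% to 2.80%), miR-276-5p, miR-282-3p, miR-276a-3p, miR-9c-5p, miR-79-3p, miR-8-5p and bantam-3p. They fell in the other arms with 1000 reads in both, such as miR-8-3p (3.11% to 0.235%), miR-184-3p (1.52% to 0.290%) and miR-263a-5p (5.01% to 1.57%). miR-11-3p stood out, with tailed reads at 5.39% in the luciferase-labelled and 10.1% in the nibbler-labelled unoxidized library and its U tails at 2.36% and 6.40%, whereas after oxidation 4.43% and 5.17% were tailed. Tailed reads were also more frequent for miR-306-5p (12.7% and 15.8%), miR-13b-2-5p (7.07% and 9.93%), miR-263a-5p (10.1% and 12.8%) and miR-998-3p (5.63% and 7.85%). After oxidation miR-263a-5p had 4.19% and 6.72%. Other arms fell in the unoxidized pair, most of all miR-996-5p (10.4% and 9.32%) and miR-308-3p (13.0% and 12.1%). The arms named here were chosen after their values were seen. Tails, mismatches inside the read and sequencing errors at the 3′ end cannot be separated read by read.

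Markers of other cell types were rare. In the luciferase-labelled and nibbler-labelled unoxidized libraries, the muscle miRNA miR-1-3p had 10 and 11 reads, the neuronal miR-124-3p 0 and 1, let-7-5p 42 and 84, miR-100-5p 15 and 10, and miR-125-5p 17 and 22. Of early embryonic miRNAs, miR-286-3p had 98 and 247 reads, miR-4-3p 707 and 260, miR-5-5p 553 and 828, miR-3-3p 20 and 19, and miR-309-3p 1 and 4. miR-310-3p, miR-311-3p, miR-312-3p and miR-313-3p had 46, 28, 198 and 11 reads against 26, 23, 131 and 12. miR-286-3p and miR-4-3p, of 1 embryonic cluster, thus passed 2-fold in opposite directions.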

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

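All tests of the missing reads, and the tests of a shift of all lengths, of a 3′ end bias and of Nibbler depletion, were chosen after the results were seen; the tests of depth and of 5′ starts on the length pattern had been chosen before.

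Reads outside the miRNA comparisons stood above the level of the other label. Luciferase-matching reads reached 96697 RPM in the luciferase-labelled oxidized and 10456 RPM in the luciferase-labelled unoxidized library, and the stretch of 2L near nibbler gave 133 and 7.54 RPM there. In the nibbler-labelled libraries, where siRNAs of nibbler would be looked for, that stretch gave 0 and 1 reads. A difference in depth is argued against, since 669 reads would be awaited at equal rates in the nibbler-labelled oxidized library. A swap of the labels is argued against by the luciferase reads, which were at least 1143 times more frequent under the luciferase label in both pairs. Removal of reads of this gene before deposit of the nibbler-labelled libraries stays open, because the count of 0 empty windows among the 455 outside the stretch follows from how the stretch was found. Carry-over of nibbler siRNAs into the luciferase-labelled libraries was not tested.

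Length changes differed between the oxidized and unoxidized pairs in miR-305-5p (-0.467 nt, oxidized minus unoxidized), miR-263a-5p (-0.403 nt) and miR-995-3p (0.577 nt). The oxidized estimates of miR-305-5p and miR-263a-5p lay below 0 with intervals that included 0, so their sign was not settled, and with 1 library per group the differences were not tested across conditions. For the 9 arms longer in the nibbler-labelled unoxidized library, a shift of equal size in all arms is argued against by the median over all 49 arms, 0.0473 nt. Of the 9 arms, 7 stayed longer relative to it. The median cannot speak to a shift that moves mainly arms with varied 3′ ends, and all 9 lay among the arms with a wide spread of lengths. Mixed 5′ starts are argued against too, as the share of the 9 arms that stayed longer was 1 with the single most abundant start. After thinning to the shallowest library that share was 0.889. Thinning leaves the expected mean length unchanged, so it checked depth only through the read minimum and counting error. A 3′ end bias shared by both nibbler-labelled libraries would act on oxidized RNA as well. Over the 8 of these arms with at least 100 reads in each oxidized library, the median oxidized change was 0.214 of the unoxidized change (counting interval -0.123 to 0.428). The arms were picked for a large unoxidized change, which can lower this ratio, and some had few oxidized reads (104 and 110 in miR-996-3p). Some were already long in the luciferase-labelled oxidized library, such as miR-305-5p (23.08 nt) and miR-263a-5p (23.44 nt). Their means in the nibbler-labelled unoxidized library were 22.86 and 23.35 nt, so few short forms were left to lengthen. Others, miR-996-3p, miR-2a-3p and miR-190-5p, were shorter after oxidation. The ratio therefore cannot decide on a bias shared by both libraries, and it cannot speak to a bias of the unoxidized library alone. Loss of trimming through Nibbler depletion may underlie the pattern, but with 1 library per group it cannot be told apart from a difference between cultures or libraries.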

How the results depend on the processing

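The alternatives relative to the median of all arms and with shared arms kept were chosen after the results were seen. Of 12 alternatives to the count of longer unoxidized arms, 10 stayed within 1.5 times of 9 (7 to 10 arms, all 9 shared or, where 7 or 8 were called, all of those shared), and the count of shorter arms stayed at 0 in 12 of 12. The count became 5 with the most abundant length and 1 with a limit of 0.5 nt, and the Nibbler list median 0 and, at 5000 reads, 0.432 nt. In the oxidized pair longer arms became 0 at 5000 reads, shorter arms 1 (miR-79-3p) at 200 reads, and the list median 0.0903 nt at 200 reads, 0.0847 nt with fully matching reads and 0.0955 nt with full read lengths. Arms with a difference of differences past the limit numbered 5 at 200 reads, 1 at 5000 reads and 1 at 0.5 nt. These counts fell at higher limits because fewer arms could pass; the cause of the other moves was not tested.

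Arms past 2-fold numbered 5 and 3 with 1000 reads and 18 and 27 with no minimum in the unoxidized and oxidized pairs. The minor-arm median after oxidation reversed to -1.95 and -2.05 as a share of all reads and to -4.95 and -5.25 against hairpin reads for luciferase-labelled and nibbler-labelled libraries. The first reversal arose because other classes take most oxidized reads. The second arose because hairpin reads rose with oxidation, from 0.20% to 1.6% and from 0.220% to 2.02% of all reads, while the miRNA share fell. The minor minus major difference became 5.99 and 5.30 with 1000 reads summed over both libraries, a limit that minor arms can pass through oxidized reads. It became 3.60 in nibbler-labelled libraries with no minimum. Hairpin scaling was not run for the unoxidized pair, as it was planned for oxidized libraries.

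By construction, subsets moved shares. The 2L stretch gave 3.95 and 112 RPM at 21 nt, 4.41 and 64.3 on the plus and 3.13 and 69.1 on the minus strand in luciferase-labelled unoxidized and oxidized libraries, and 0 at 21 nt and 0 on the plus strand in the nibbler-labelled unoxidized one. In the order luciferase-labelled then nibbler-labelled, unoxidized then oxidized, tails of 1 nt made up 1.74%, 1.79%, 0.992% and 0.987%, and the median tailed share over arms was 5.79%, 6.45%, 4.43% and 4.77%. The miRNA share was 90.5%, 91.0%, 15.6% and 22.3% of reads with 1 place and 56.2%, 53.3%, 1.26% and 1.52% of 21-nt reads. The peak length held 14.5%, 14.8%, 78.2% and 77.5% of distinct sequences. In the oxidized pair 23 arms had 1000 reads against 49 in the unoxidized pair, where 46 were left after thinning to the shallowest library, so the low share of miRNA reads after oxidation, more than total depth, limits the oxidized pair.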

Other observations

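The 3′ ends of arms in the luciferase-labelled library were compared with their change in the nibbler-labelled one, a test chosen before the result was seen; the test of oxidation, and those of the 5′ end, of the whole hairpin and of scaling below, were chosen after it. The hypothesis that arms with varied 3′ ends lengthen more had a Spearman coefficient of 0.509 across 49 arms, which are not independent replicates. The median change was 0.124 nt in arms with a wide spread of lengths and 0.0211 nt in arms with a narrow one, and all 9 arms called longer lay in the first group. The spread came from the same library as the mean subtracted in the change, so the measures are not independent. It also includes reads whose match is cut short by mismatches, as in miR-305-5p (SD 2.68 nt). The hypothesis that the lengthened arms are longer after oxidation in luciferase-labelled cells was left open, as the share that were longer was 0.556. miR-305-5p, miR-2b-3p, miR-263a-5p, miR-34-5p and miR-9b-5p were longer, by 0.633, 0.626, 0.469, 0.433 and 0.411 nt, and miR-996-3p, miR-2a-3p, miR-190-5p and miR-317-3p were shorter, by -1.01, -0.851, -0.819 and -0.452 nt.

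Abundance changes shared by the oxidized and unoxidized pairs, led by miR-79-3p, miR-317-3p, miR-252-5p and bantam-5p, could come from biases of the libraries. A change of the whole hairpin is argued against for most of them. Over 8 arms past 2-fold in the unoxidized pair, the other arm moved by a median of 0.0923 of their log2 change. Some of these, such as miR-279-5p and miR-970-5p, were not measured in the oxidized pair. For the arms past 2-fold in both pairs the ratio was 0.0160 (bantam-5p), 0.0687 (miR-306-3p), 0.138 (miR-317-3p), 0.224 (miR-79-3p) and 0.605 (miR-252-5p). A change of the mir-252 hairpin stays open. Scaling by dominant arms would move all arms alike and is argued against as the cause of all 10 changes of the unoxidized pair. The share in the commoner direction was 0.5, with 5 arms higher and 5 lower. Of the arms past 2-fold in both pairs, miR-79-3p, miR-317-3p, miR-252-5p and miR-306-3p were lower and bantam-5p was higher. The test therefore does not settle scaling for the shared changes alone. A 5′ end sequence bias stays open, because reads with another 5′ start moved by a median of 0.737 of the change of the main start over 4 arms, from 0.577 in miR-317-3p to 1.03 in miR-79-3p. Differences between cultures of the labelled groups were not tested.

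Among 21-nt reads outside the named classes, the first 4 bases varied more between labels than the last 4. The SD of the log2 ratio, nibbler-labelled over luciferase-labelled, was 0.29 for the first 4 and 0.18 for the last 4 bases in unoxidized libraries, and 0.21 and 0.10 in oxidized libraries.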
